A study of Homo sapiens with 15 samples.

How the data were processed

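Chromatin immunoprecipitation with sequencing was carried out in MCF-7, a human luminal breast cancer cell line that expresses the estrogen receptor. Per the labels' protocols, cells were kept without hormone for 72 h and then given 100 nM 17-beta-estradiol for 0 h, 45 min or 3 h. There were 15 samples, 1 per group. Of these, 12 were the time course of 4 antibodies (CTCF, estrogen receptor or ER, FOXA1 and Lamin B) at 3 times. A further 2 were ER samples from cells given a small interfering RNA against CTCF (siCTCF) or a non-targeting one (siNT), and 1 was an input sample with no peak list, which was not used here. The labels of the siCTCF and siNT samples give no estradiol time. Their deposited files are tagged 45 min, which was not used to set groups. The CTCF list of 45 min was chosen before the data were examined as the one for the tests on knockdown peaks, with the union of the 3 times as an alternative.

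Each of the 14 samples used had 1 list of peaks with a position and a value per peak. Bowtie2, SAMtools and MACS2 and the hg19 build are named, without versions, per the submitters' processing notes. Read depths, filters, the control used for each list and any pooling of samples are not given in the sources used here. In the 12 time-course lists the deposited value of a peak is a score whose scale no header states. It started at 50 in every one of these lists and reached from 1090 to 3233. In the 2 knockdown lists the deposited value is read as −log10 of a q value from the names of the peaks, and it started at 2.01 and 2.04. Values of the 2 sorts were never compared, and tests used a value only to rank, match or cut peaks within a list. Medians of the score and counts above a common score are set side by side for time-course lists as description, and the unstated scale limits what they show. Many peaks tie at a score of exactly 3100 in the 7 lists described next as holding unplaced sequences. Positions are hg19 and are printed counting from 1.

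The time-course lists fell into 2 kinds. The CTCF, ER and FOXA1 lists at 0 h and 45 min and the Lamin B list at 45 min (7 lists) held peaks on unplaced sequences. The CTCF, ER and FOXA1 lists at 3 h and the Lamin B lists at 0 h and 3 h (5 lists) held none, and no peak in them was wider than 11928 bp, against at least 54545 bp for the widest peak of each of the other 7. Kind is therefore treated as a technical batch. A change from 0 h to 45 min is within 1 kind for ER, CTCF and FOXA1, and a change from 0 h to 3 h is within 1 kind for Lamin B. All other comparisons over time cross the kinds, and kind and time cannot be told apart in them.

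A peak was shared when it overlapped a peak of the other list by at least 1 bp. Shares have Wilson 95% binomial intervals, which cover counting error only. With 1 library per group no comparison of times or of knockdown arms has a replicate check, and no p-value is given for one. The p-values describe places within these lists. For co-occupancy, the peaks of the first list on the assembled chromosomes were shifted at random around each chromosome 1000 times. Shifts were of at least 1 Mb, and chromosome lengths were taken as the highest position in any list. The overlap was divided by its mean over the shifts, with a one-sided permutation p adjusted over 18 tests by Benjamini-Hochberg. The map of all pairs of the 14 lists used 200 shifts. For subsets of peaks, the share with a second factor was set against 1000 random sets of the same size from the whole list, matched on peak value in 20 bins. These tests had a two-sided permutation p, adjusted over 10 tests, of which the 2 on peaks gained under knockdown were added after the lists were seen. The matched sets could contain members of the subset, so their ratios lie nearer to 1 than a comparison with the remaining peaks would. Peaks on unplaced sequences were kept in these tests, and none of their alternatives left only those sequences out.

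Alternatives were a stricter common threshold (the highest of the lists' medians), lists cut at their median value, an overlap of 50% of the shorter peak, equal numbers of the strongest peaks, matching on width, shifts of 50 to 500 kb, the union of the 3 times, the 3 h lists, and leaving out unplaced and Y sequences or the 5234 regions with a time-course peak of all 4 factors. Cutting peaks to 200 bp around their midpoints was added after the widths were seen. Shifts of 50 to 500 kb for all pairs of the 12 time-course lists (200 shifts) were added later, after all other results were seen. Regions are named by a rule set before the data were examined. For each comparison over time or knockdown it takes the 5 peaks of highest value in one list and absent from the other, in each direction, and the 3 highest shared by all lists compared. The text prints examples from these. The gene table at hand is of another assembly (GRCh38.p14), so gene annotation of peaks, sequence motifs and the lists of genes and cell markers planned for them were not analysed here.

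Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9 were used. Overlap counts were checked against bedtools 2.31.1, which gave the same 2201 ER 45 min peaks at CTCF 45 min peaks. On simulated lists of the size of the ER 45 min list, the shift test had p under 0.05 in 13 of 200 runs with no planted overlap. The simulated peaks were placed evenly at random along each chromosome. This rate therefore does not show how the test behaves for lists clustered in the same parts of a chromosome. The shift test recovered a planted overlap of 20% as 19.9%. On the siNT list with FOXA1 0 h as the second factor, the matched test returned a mean ratio of 1.01 for no effect, with p under 0.05 in 1 of 40 runs. For a planted odds factor of 2 it returned 1.62, with p under 0.05 in 40 of 40 runs. Loss was planted for each peak independently, and the matched sets also ignore where peaks lie. These runs therefore do not show how the matched test behaves where neighbouring peaks go together.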

Results

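Binding of CTCF, ER, FOXA1 and Lamin B was mapped in MCF-7 cells before and after estradiol, and ER binding was also mapped after CTCF knockdown. CTCF is a zinc-finger protein that binds insulators, ER is the hormone-activated receptor, FOXA1 is a forkhead factor able to bind closed chromatin, and Lamin B is a filament protein of the nuclear lamina. The design asks where the 4 proteins bind over 3 times and whether loss of CTCF changes ER binding. Each of the 14 lists comes from 1 library, so nothing below has a replicate check. The lists held from 4736 to 49744 peaks and covered from 4.62 to 43.8 Mb. Read depth is unknown, so peak numbers cannot be corrected for it.

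At 45 min of estradiol the ER list held 13448 peaks, 1.57 times the 8541 at 0 h, and both lists were of the kind with unplaced sequences. Of the 45 min peaks, 18.1% (95% interval 17.4 to 18.7) were already present at 0 h and 11020 were not. The ER peaks present at both times had a median score of 202 at 45 min, against 91.1 for those absent at 0 h. In the other direction, 26.0% (25.1 to 27.0) of the 0 h ER peaks were found at 45 min. Among ER peaks absent at 0 h, the highest scores at 45 min were at chromosome 17, 49021674 to 49022220 (score 3100), chromosome 20, 49380300 to 49381267 (3100), and chromosome 20, 46704550 to 46705335 (2995). All 3 regions also had a FOXA1 peak at 0 h and an ER peak in both knockdown lists. The next ER region, chromosome 1, 112055974 to 112056498 (2779), was in no other time-course list but in both knockdown lists.

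Among ER peaks of 0 h absent at 45 min, the region with the highest score, chromosome 2, 223763301 to 223764417 (score 2860), carried CTCF and FOXA1 peaks at 0 h as well and ER peaks in both knockdown lists, as did chromosome 5, 98774215 to 98774808 (2827). Chromosome 5, 89857891 to 89858217 (1365) carried CTCF and FOXA1 peaks at 0 h only, while chromosome 6, 58773481 to 58780313 (1655) was in no other list. At 3 h the ER list held 25096 peaks, 2.94 times the number at 0 h, but only 7.50% of the 0 h ER peaks (6.97 to 8.08) were among them. Of the tenth of ER peaks with the highest scores at 45 min, 2.38% (1.69 to 3.34) had a peak at 3 h. The highest ER peaks at 3 h absent at 0 h included chromosome 5, 39787606 to 39794053 (score 787), which is 6448 bp wide and also had CTCF, FOXA1 and Lamin B peaks. Just 312 merged ER regions, 0.747% of 41781, had a peak at all 3 times. The 3 h ER list is of the other kind, so time and kind cannot be told apart there. It also lay at Lamin B peaks of 0 h for 49.1% of its peaks (15.4 times the shifts) and at siNT ER peaks 0.331 times as often as the shifts. Other lists of its kind share these traits in part, with 37.0% and 0.314 times for CTCF 3 h and 45.4% and 2.38 times for FOXA1 3 h. Whether the lists of either kind hold the binding their labels name could not be settled here. Among ER lists of the kind with unplaced sequences, that of 0 h lay at siNT ER peaks 0.938 times as often as the shifts and that of 45 min 4.18 times. At a common score of at least 115 the ER ratio of 3 h to 0 h turned to 0.734, while that of 45 min to 0 h was 1.39.

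CTCF had 23168 peaks at 0 h and 18302 at 45 min, both in lists of the kind with unplaced sequences, a ratio of 0.790. CTCF peaks were shared most often where they were strong. Of the tenth of 45 min CTCF peaks with the highest scores, 80.4% (78.5 to 82.1) were present at 0 h, against 18.03% (16.3 to 19.9) of the tenth with the lowest scores. Over the whole list it was 38.1% (37.4 to 38.8). Many high scores tie, with 520 CTCF peaks of 45 min at exactly 3100, so the named CTCF regions of that score are not ranked among themselves. Those absent at 0 h included chromosome 12, 89095336 to 89096885, which also had ER and Lamin B peaks at 45 min, and chromosome 13, 41973411 to 41974391, which also had FOXA1 and Lamin B peaks at 45 min. The strongest CTCF regions of 0 h absent at 45 min, chromosome 2, 176098279 to 176098581 and 205204628 to 205204920 (score 3196 each), both carried ER and FOXA1 peaks at 0 h. The direction of the number turned with the threshold, since 9190 CTCF peaks at 45 min and 7631 at 0 h had a score of at least 625, a ratio of 1.20.

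The 3 h CTCF list was about as long, with 19901 peaks, but it lay mostly elsewhere. It held 1.42% (1.02 to 1.99) of the tenth of 0 h CTCF peaks with the highest scores and 32.6% (30.8 to 34.6) of the tenth with the lowest. Its median score was 64.5 against 457 at 0 h, its median peak width 679 bp against 313 bp, and 7 of its peaks reached a score of 625. Its highest CTCF peaks absent at 0 h were at chromosome 9, 140459634 to 140463165 (score 1090) and chromosome 4, 189365885 to 189370089 (821). This list is of the kind without unplaced sequences, so no within-kind value of CTCF at 3 h exists.

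FOXA1 had 28863 peaks at 0 h and 4736 at 45 min, a ratio of 0.164 within 1 kind of list. The 45 min list held 4.97% (4.72 to 5.23) of the 0 h FOXA1 peaks, and 9.39% (8.38 to 10.5) of the tenth with the highest scores. In the other direction, 28.4% (27.1 to 29.7) of the 45 min FOXA1 peaks lay at a 0 h peak. It was 65.8% (61.4 to 69.9) for the tenth with the highest scores and 20.3% (16.9 to 24.2) for the tenth with the lowest. These shares include unplaced sequences. On assembled chromosomes 24.7% of the 4103 FOXA1 peaks of 45 min lay at a 0 h peak. Strong FOXA1 regions of 0 h without a peak at 45 min included chromosome 3, 61620075 to 61620855 (score 3194), chromosome 6, 100966309 to 100967094 (3181) and chromosome 8, 29184380 to 29185918 (3168). All 3 had a FOXA1 peak at 3 h and an ER peak in both knockdown lists, whereas chromosome 20, 52682811 to 52685011 (3187) had the former and not the latter. The FOXA1 peaks seen at 45 min and not at 0 h were led by chromosome 16, 10592355 to 10593715 (955), which also had CTCF and Lamin B peaks at 45 min. Chromosome 20 had 5.42 times and chromosome 17 had 4.12 times the mean peak density of the FOXA1 45 min list, against 1.94 and 1.82 times in the 0 h list. At 3 h, across list kinds, FOXA1 had 20268 peaks. They included 11.6% (11.2 to 11.97) of all 0 h FOXA1 peaks and 39.8% (38.0 to 41.6) of the tenth with the highest scores.

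Lamin B had 37012 peaks at 0 h and 14975 at 3 h, a ratio of 0.405 within the kind without unplaced sequences. Of the 3 h Lamin B peaks, 42.6% (41.8 to 43.4) were present at 0 h, and of the tenth with the highest scores 72.9% (70.6 to 75.1). At a distance of 10 kb, peaks of Lamin B lay singly more often than in runs. This distance cannot show whether peaks gather over longer stretches. Joined within 10 kb, the 37012 peaks of 0 h formed 31371 clusters, of which 842 held at least 3 peaks, and the 14975 of 3 h formed 13868 clusters, of which 106 did. The highest Lamin B region shared by all 3 times was chromosome 16, 10592313 to 10593766 (score 2837 at 0 h), the place that also led the FOXA1 45 min peaks absent at 0 h. Lamin B at 45 min, in the other kind of list, had 5903 peaks and held 1.48% (1.36 to 1.61) of the 0 h peaks. Its 5180 peaks on assembled chromosomes formed 4267 clusters, of which 155 held at least 3 peaks and the largest held 29. Chromosome 20 had 4.71 times the mean peak density in that list and 0.896 times at 0 h.

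**Figure D1:**
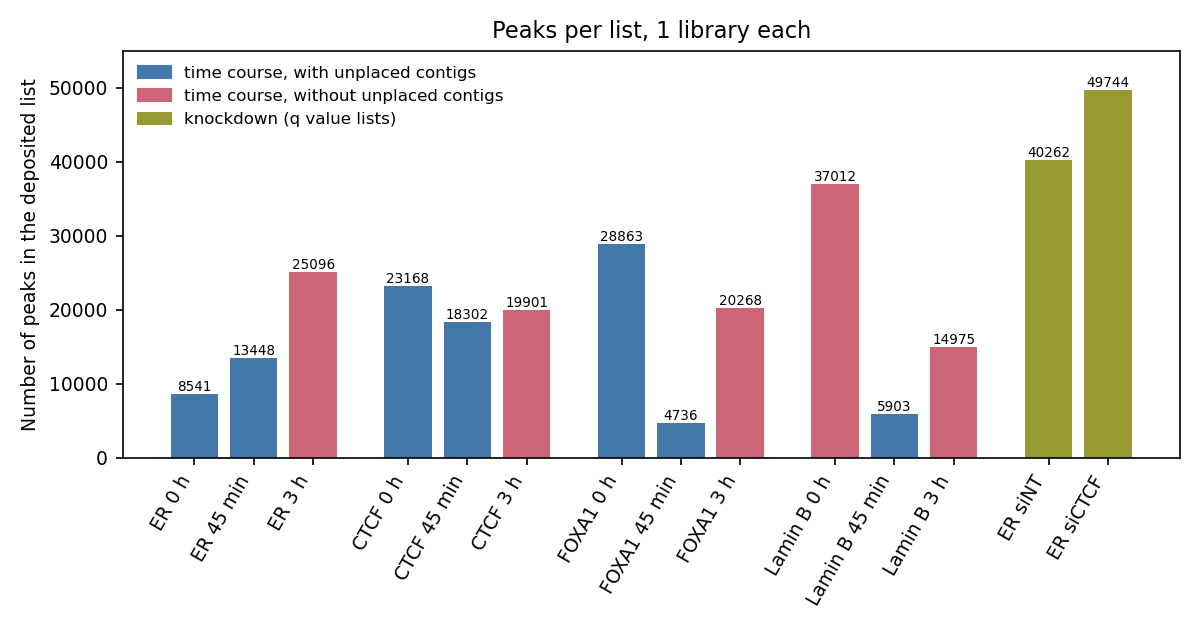
Number of peaks (vertical axis) in each of the 14 lists (horizontal axis), 1 library per bar, with bar colour giving the kind of list. From 0 h to 45 min, in lists of the same kind, ER goes from 8541 to 13448 peaks and FOXA1 from 28863 to 4736, while Lamin B at 45 min (5903) is the one Lamin B list with unplaced sequences.

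**Figure D2:**
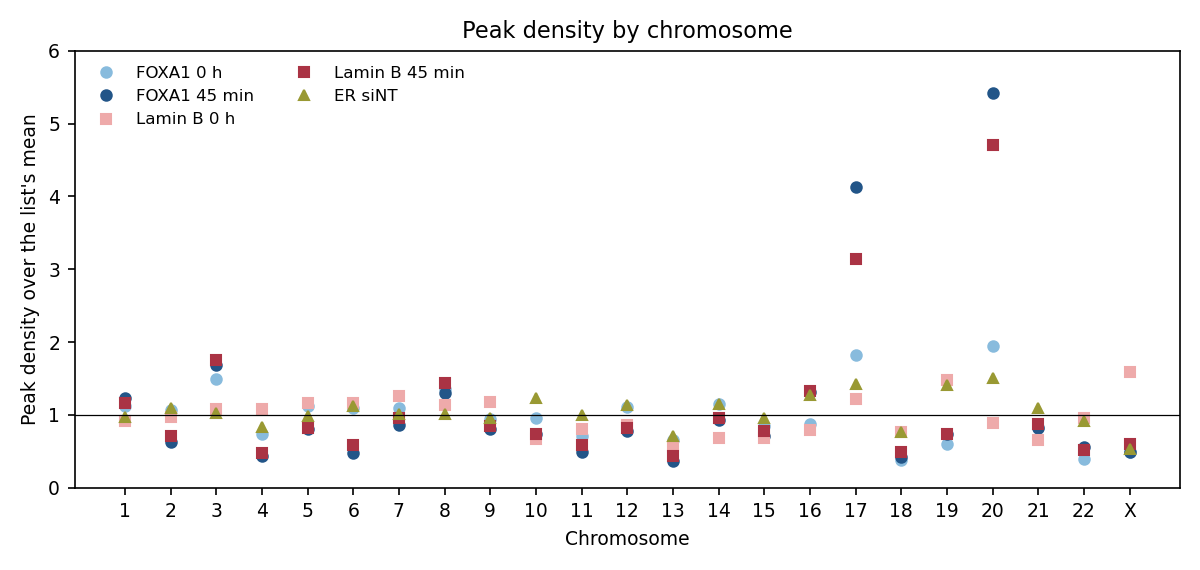
Peak density on each chromosome relative to the mean of its list (vertical axis) for 5 lists, 1 library each, with the line at 1 marking the mean. FOXA1 45 min (5.42) and Lamin B 45 min (4.71) stand out on chromosome 20 against 1.94 for FOXA1 0 h and 0.896 for Lamin B 0 h.

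In the time-course lists, peaks of the 4 proteins were found at the same places far more often than in shifted lists. The siNT ER list did not show this for CTCF, at 1.06 times the shifts for CTCF 0 h and 0.989 times for CTCF 45 min. It did for FOXA1 0 h, at 15.3 times. At 0 h, 35.7% (34.6 to 36.7) of ER peaks overlapped a CTCF peak, 44.7 times the mean of the shifts, and 23.9% (22.9 to 24.8) overlapped a FOXA1 peak, 18.7 times. At 45 min the ER share at CTCF was 15.7%, 22.6 times the shifts, and the ER share at FOXA1 was 7.78%, 30.9 times. FOXA1 and Lamin B went from 1.82 times the shifts at 0 h to 54.7 times at 45 min, when 29.2% of FOXA1 peaks overlapped a Lamin B peak, and 13.4 times at 3 h. These folds depend on how places are drawn. With shifts of 50 to 500 kb, which keep peaks in their neighbourhood, ER at 0 h was at 22.2 times the shifts for CTCF and 8.75 times for FOXA1, FOXA1 and Lamin B at 45 min were at 6.07 times the shifts, below 13.0 times at 3 h, and ER at 45 min was at 12.6 times for CTCF and 6.71 times for FOXA1, the opposite order. With lists cut at their median score ER and CTCF at 0 h were at 125 times. At 3 h all 6 pairs of proteins lay between 12.3 and 19.3 times the shifts. In all 18 tests none of the shifts reached the observed overlap (adjusted p = 0.001, one-sided permutation test over places, the smallest that 1000 shifts can give). The Lamin B list of 0 h is of another kind than the other 0 h lists, and its overlap with FOXA1 turned below the shifts, to 0.668 times, when lists were cut at their median score. Differences of these folds between times were not tested.

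The pairs followed the kind of list as well as the protein. Different proteins in the 5 lists without unplaced sequences overlapped with a median fold of 13.3 over shifts, and different proteins in the 7 lists with them 28.5. The same protein across kinds had a median fold of 6.86, next to 6.68 for different proteins across kinds. Within a kind, the same protein had 15.6 in the 5 lists, from Lamin B 0 h and 3 h alone, counted both ways. In the 7 lists it had a median of 36.7 over 6 ordered pairs, which ranged from 14.1 to 67.4. With shifts of 50 to 500 kb the order of the first pair of values turned, to 12.8 for the 5 lists and 8.50 for the 7. The same protein across kinds then had 7.39, and within the 5 and the 7 it had 14.2 and 15.4. The last of these ranged from 3.53 to 39.3. Across kinds, folds over shifts of at least 1 Mb differed by protein. FOXA1 0 h lay at FOXA1 3 h 8.27 times, against 1.94 for CTCF 3 h, 2.00 for ER 3 h, 1.82 for Lamin B 0 h and 2.09 for Lamin B 3 h. CTCF 0 h lay at CTCF 3 h 9.42 times, against 12.8 for FOXA1 3 h, 9.74 for ER 3 h, 10.4 for Lamin B 0 h and 8.55 for Lamin B 3 h.

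**Figure D3:**
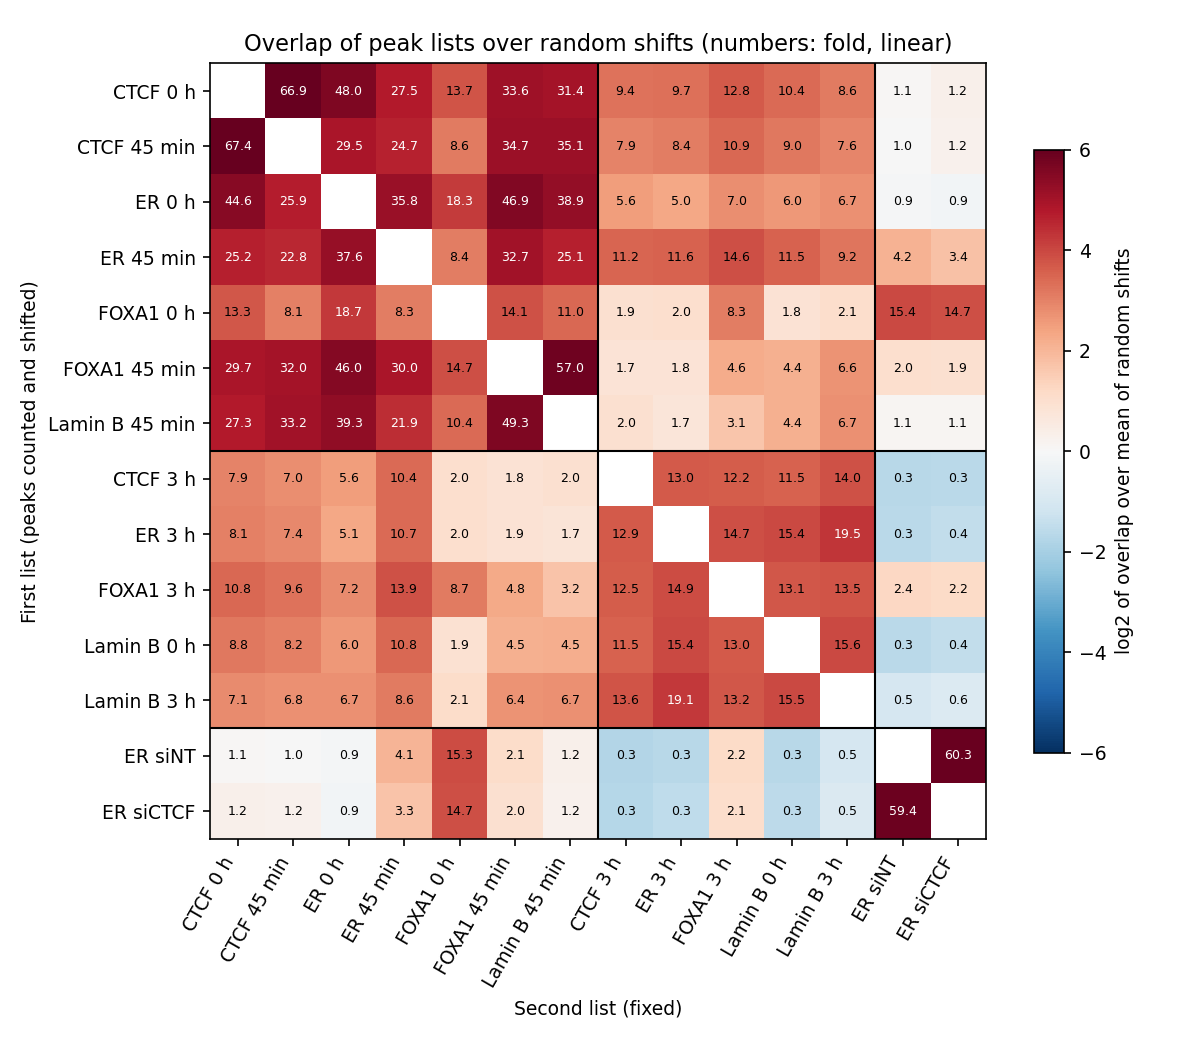
Overlap of each list (rows) with each other list (columns), as fold over the mean of random shifts, with numbers linear and colour on a log2 scale. Lines part the 7 time-course lists with unplaced sequences, the 5 without, and the 2 knockdown lists; CTCF 0 h with 45 min (66.9) and siNT with siCTCF (60.3) stand high, and the knockdown lists reach 15.3 at FOXA1 0 h.

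The next comparisons asked whether ER went to places FOXA1 or CTCF already held. Of all ER peaks of 45 min on assembled chromosomes, 10.8% overlapped a FOXA1 peak of 0 h, 8.39 times the shifts, and 20.7% a CTCF peak of 0 h, 25.2 times. The subsets that follow were taken from whole lists, with unplaced sequences, so their shares have another base. On assembled chromosomes 2045 ER peaks of 45 min were present at 0 h, against 2428 in the whole list. How far unplaced sequences raise the shares was not tested. Of the 11020 ER peaks present at 45 min and absent at 0 h, 6.27% (5.83 to 6.74) overlapped a FOXA1 peak of 0 h. This compares with 43.6% (41.6 to 45.6) of the 2428 ER peaks present at both times. CTCF peaks of 0 h lay at 14.2% (13.5 to 14.8) of the ER peaks absent at 0 h and at 54.4% (52.4 to 56.4) of those present at both times. Sets of ER peaks matched on score gave 11.2% at FOXA1 and 20.4% at CTCF, so the ratios were 0.562 and 0.694. ER peaks of 0 h themselves lay often at FOXA1 and CTCF peaks of 0 h, so leaving them out lowers these shares by itself, and ratios below 1 do not mean that ER avoided places already held. Likewise, of 11333 CTCF peaks present at 45 min and absent at 0 h, 9.65% (9.12 to 10.2) lay at an ER peak of 45 min, against 20.5% (19.6 to 21.5) of the 6969 CTCF peaks present at both times, a ratio of 0.688 to matched sets. Each of the 3 had an adjusted p of 0.00285 in the two-sided permutation test over peaks, from the smallest raw p that 1000 sets can give, 0.002. All lists here are of 1 kind. With the 3 h lists, which cross kinds, the ratios were 0.925, 0.943 and 0.932. Peaks absent at 0 h made up 24459 of 25096 ER peaks and 17956 of 19901 CTCF peaks there. Matched sets held mostly the same peaks, so these ratios lie near 1 by construction. FOXA1 peaks of 0 h lay at 3.25% of the ER peaks absent at 0 h, against 14.8% of those present at both times. For CTCF peaks of 0 h it was 9.003% against 33.1%, and for ER at CTCF peaks 27.2% against 62.6%.

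Lamin B at CTCF peaks was compared for CTCF peaks with and without ER. At 45 min 35.9% (34.0 to 37.8) of the 2523 CTCF peaks with an ER peak also had a Lamin B peak, against 6.19% (5.82 to 6.57) of those without ER, and the ratio to score-matched CTCF peaks was 2.76. At 3 h it was 35.3% (34.1 to 36.5) of 6105 against 8.97%, a ratio of 1.73. At 0 h it was 11.8% (10.7 to 12.9) of 3422 against 19.6%, a ratio of 0.910. Adjusted p values were 0.00285 at 45 min and at 3 h and 0.020 at 0 h in the two-sided permutation test over peaks. The CTCF peaks of 45 min include 333 on unplaced sequences, and on assembled chromosomes 2260 of them had an ER peak, against 2523 in all. The share of these 2260 with Lamin B was not computed, so how far unplaced sequences raise the 35.9% is unknown. The 3 h lists hold no such sequences. The lists are of 1 kind at 45 min and at 3 h but not at 0 h, where the ratio turned to 1.08 with lists cut at their median score. Different proteins overlapped more within a kind (median folds 13.3 and 28.5 over shifts) than across kinds (6.68). The ratios above and below 1 therefore follow the kind of list as well as time, and the 2 cannot be told apart here. Leaving out the regions of all 4 factors removes CTCF peaks with ER and Lamin B by definition where the region also holds a FOXA1 peak. Falls in the share with Lamin B are therefore partly built in. This cut left 6.93% (5.63 to 8.50) of CTCF peaks with ER against 5.34% of those without at 45 min (ratio to matched 1.81), 26.7% (25.1 to 28.3) against 8.52% at 3 h (2.10) and 3.94% (3.20 to 4.84) against 9.90% at 0 h (0.604).

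In the knockdown comparison the ER list of siCTCF cells held 49744 peaks, 1.24 times the 40262 of siNT cells. Of the siNT ER peaks, 93.7% (93.4 to 93.9) were present in siCTCF cells, including every one of the 4026 with the highest values. Of the siCTCF ER peaks, 74.9% (74.5 to 75.3) were present in siNT cells, including every one of the highest 4974. The 2547 siNT peaks absent from siCTCF were weak, with a median −log10 q of 8.57 against 28.7 for shared peaks. The 12474 siCTCF peaks absent from siNT had a median of 8.78 against 39.9 for shared ones. The strongest ER peaks absent from siCTCF were at chromosome 12, 104245532 to 104246064 (−log10 q 89.0) and chromosome 6, 26212202 to 26212630 (54.1). The strongest absent from siNT were at chromosome 2, 234395544 to 234396837 (93.7), which had a FOXA1 peak at 0 h, chromosome 9, 95468707 to 95469224 (90.8), and chromosome 2, 11828492 to 11828968 (89.8), which had a CTCF peak at 0 h. The level of CTCF itself is not measured by an ER immunoprecipitation, so the knockdown could not be checked, and with equal numbers of the strongest peaks 86.5% were shared.

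CTCF peaks lay at few ER peaks of either knockdown list, and at fewer of those lost than of those kept. CTCF peaks of 45 min lay at 0.509% of siNT ER peaks, 0.989 times the shifts, so the siNT subsets are parts of an overlap no larger than in shifted lists. For siCTCF ER peaks it was 0.647%, 1.21 times the shifts (one-sided permutation p = 0.00498, unadjusted, the smallest that 200 shifts can give). Of the 2547 siNT ER peaks absent from siCTCF, 3 (0.118%, 0.0401 to 0.346) overlapped a CTCF peak of 45 min, against 0.536% (0.467 to 0.614) of those kept and 0.409% of value-matched siNT peaks (ratio 0.288, adjusted p = 0.020, two-sided permutation test over peaks). FOXA1 peaks of 0 h lay at 6.75% (5.84 to 7.79) of the lost ER peaks and at 16.0% (15.7 to 16.4) of those kept (ratio to matched 0.467, adjusted permutation p = 0.00285). Among siCTCF ER peaks absent from siNT, 0.842% (0.696 to 1.02) overlapped CTCF, against 0.585% (0.512 to 0.668) of the rest (ratio to matched 1.63, adjusted permutation p = 0.00285). FOXA1 lay at 12.7% (12.2 to 13.3) of the same peaks, and the ratio of 0.976 did not pass the test (adjusted permutation p = 0.130). The CTCF result on lost peaks rests on 3 overlaps and did not pass with lists cut at their median value (ratio 0.608, permutation p = 0.482) or with an overlap of 50% (0.528, permutation p = 0.310). The FOXA1 ratio for gained peaks turned to 1.18 with lists cut at their median value and 1.19 with matching on width, and both comparisons of gained peaks were chosen after the lists were seen.

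**Figure D4:**
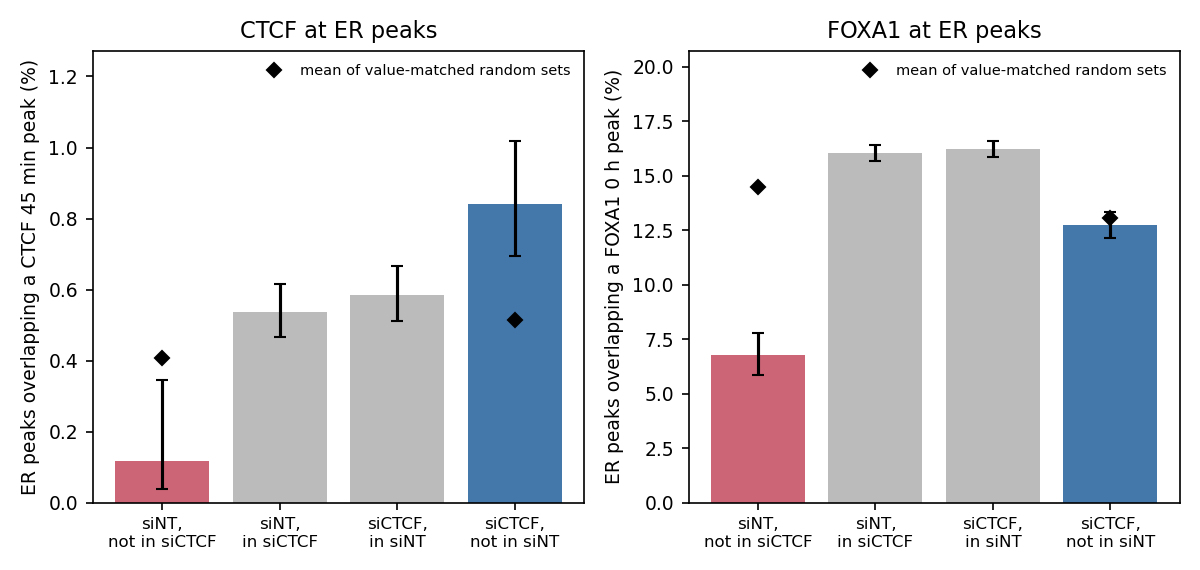
Percent of ER peaks (vertical axes, different scales) that overlap a CTCF 45 min peak (left) or a FOXA1 0 h peak (right), for siNT and siCTCF peaks absent from or present in the other list; bars carry Wilson 95% intervals and diamonds are the mean of value-matched random sets. For lost siNT peaks the bars (0.118% for CTCF, 6.75% for FOXA1) lie below the diamonds (0.409% and 14.5%), and for gained siCTCF peaks the CTCF bar (0.842%) lies above it (0.515%).

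The knockdown control was also set beside the time course. FOXA1 peaks of 0 h lay at 15.5% (15.1 to 15.8) of siNT ER peaks, 15.3 times the shifts, and ER peaks of 45 min at 2.16% (2.03 to 2.31), 4.10 times. Among the 4026 siNT peaks with the highest values the shares were closer, 20.2% for FOXA1 and 16.2% (15.1 to 17.4) for ER 45 min, and among the 4026 with the lowest they were 16.2% and 0.124%. ER peaks of 0 h lay at 0.293% of siNT peaks, 0.924 times the shifts, and ER peaks of 3 h at 0.452%, 0.315 times. Of the tenth of 45 min ER peaks with the highest scores, 29.3% (26.9 to 31.8) were in the siNT list. The estradiol time of the siNT cells is not given in the labels (their deposited files are tagged 45 min), and the lists differ in the sort of value.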

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

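Tests written only after the results they measure were seen were those of a shared batch, its repeat with shifts of 50 to 500 kb, those of estradiol at 3 h, of estradiol moving FOXA1 and of extra DNA copies, the repeat with siNT peaks cut to 200 bp, and the rule that the interval of the FOXA1 ratio of strongest to weakest peaks must lie below its bound.

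ER was set apart from the other proteins because its list grew after estradiol where theirs shrank. These differences were not tested, since each time has 1 library. From 0 h to 45 min the ER ratio of peak numbers was 1.99 times that of CTCF, 9.60 times that of FOXA1 and 9.87 times that of Lamin B. From 0 h to 3 h it was 3.42 times that of CTCF, 4.18 times that of FOXA1 and 7.26 times that of Lamin B. The comparison with Lamin B at 45 min and all those at 3 h involve lists of different kinds, and at a stricter common threshold the CTCF ratio at 45 min turned to 1.20 and the ER ratio at 3 h to 0.734.

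The 5 lists without unplaced sequences shared places across proteins. Their pairs of different proteins had a median fold of 13.3 over shifts, above the 6.86 of the same protein across kinds, and with shifts of 50 to 500 kb 12.8 against 7.39. The other 7 lists had 28.5 and 8.50, so sharing across proteins is not special to the 5. Estradiol at 3 h as the reason is argued against by Lamin B at 0 h, without estradiol. It overlapped the 3 h lists of the other proteins at a median fold of 13.0, against 13.5 among the 3 h lists. Chance overlap of wide peaks is argued against by the 13.3 itself, because the shifts keep peak widths. With peaks cut to 200 bp the median fold was 75.4. That rise is not further evidence, since the cut lowers the overlap of shifted peaks. For ER and CTCF at 3 h the mean over shifts went from 473 to 67.0 peaks, and the observed overlap from 6129 to 5200. A shared library or list-processing batch remains a candidate explanation, and an effect of estradiol on ER, CTCF or FOXA1 at 3 h stays open beside it, since no 3 h list is of the other kind.

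FOXA1 had 0.164 times as many peaks at 45 min as at 0 h. Lower depth or enrichment that keeps the strongest sites was left open. Of the tenth of strongest 0 h peaks 9.39% (8.38 to 10.5) were found, but the number of shared peaks allows at most 49.7%. The ratio to the weakest peaks, 1.43 (1.20 to 1.71), reaches the bound of 1.5 set for it. Of the tenth of strongest 45 min peaks, 65.8% lay at 0 h peaks. That share includes unplaced sequences, and it was not computed without them. Background following extra DNA copies may contribute: 22.7% (21.3 to 24.2) of the 3089 FOXA1 45 min peaks absent at 0 h and on assembled chromosomes lay in the 31 of 3109 windows of 1 Mb richest in Lamin B 45 min peaks, against 6.72% of FOXA1 0 h peaks. The windows were chosen by Lamin B 45 min peaks, at which FOXA1 45 min peaks lay 54.7 times as often as the shifts. Any background shared by these 2 lists would give this result, so it cannot single out DNA copies. The windows held 6.11% of CTCF peaks at 45 min against 5.75% at 0 h, and 7.85% of ER peaks against 9.95%. DNA copies were not measured here, and background shared by every antibody was left open by the 37.0% (35.4 to 38.6) of all 3393 FOXA1 45 min peaks absent at 0 h with a peak of another protein at 45 min. Estradiol moving FOXA1 also stays open, as Lamin B, across kinds, had a ratio of 0.159.

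ER peaks of siNT cells lay at FOXA1 0 h peaks more often (15.5%) than at ER 45 min peaks (2.16%), a gap that narrows to 20.2% against 16.2% among the siNT peaks with the highest values. The length of the FOXA1 list is argued against by 10.9% (10.6 to 11.2) with that list cut to the 13448 strongest peaks, and weak peaks filling the ER 45 min list, as the whole cause, by the 29.3% (26.9 to 31.8) of the tenth of its strongest peaks found in the siNT list, below 49.9% for FOXA1 0 h, but over whole lists it was 6.499% against 21.5% and in the tenth of weakest peaks 0.149% against 3.78%, so weak peaks as part of the cause stay open. As a hypothesis, FOXA1 may already occupy places where ER binds. FOXA1 lay at 20.2% (19.01 to 21.5) of the 4026 siNT peaks with the highest values. It lay at 16.2% (15.1 to 17.3) of the 4026 with the lowest (18.6% and 16.1% with peaks cut to 200 bp). The peaks with the lowest values were not below the whole list (15.5%). The share therefore showed no steady rise with peak value, and the hypothesis stays open. For ER 45 min the shares at the same highest and lowest peaks were 16.2% and 0.124%. The estradiol time of the knockdown cells, absent from the labels, and the different sort of list were not tested.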

How the results depend on the processing

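The choices were set before the data were examined, except the 200 bp windows, shifts of 50 to 500 kb by kind of list, all results on gained knockdown peaks and the tests named as later at the head of the patterns weighed. For co-occupancy 105 of 108 alternative values kept direction and side of the threshold, for matched tests 38 of 43. Sizes moved more: with shifts of 50 to 500 kb ER with CTCF at 0 h went from 44.7 to 22.2 times (125 with lists cut at their median), ER with FOXA1 at 0 h from 18.7 to 8.75, and at 45 min FOXA1 with Lamin B from 54.7 to 6.07 times, ER with FOXA1 from 30.9 to 6.71 and ER with Lamin B from 24.3 to 5.93, while the 3 h pairs lay between 11.2 and 17.8. Of peak number ratios 19 of 26 stayed within 1.5 times on the same side of 1, and of shared percents 13 of 44 stayed within the interval. Where values moved, the cause was not tested. Read depth, unknown here, limits all peak numbers. Leaving out replicates and paired fits need replicates, of which there are none, and the planned distances to genes and motif windows were not run. Ratios of CTCF 3 h to 0 h rest on 7 peaks at the stricter threshold.

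At the stricter threshold the ratio to 0 h was 0.734 (ER 3 h, reversed), 1.20 (CTCF 45 min, reversed), 0.000917 (CTCF 3 h), 0.0532 and 0.151 (FOXA1 45 min and 3 h), and 0.285 and 0.153 (Lamin B 45 min and 3 h). The percent of 0 h peaks shared there was 0.796 (ER 3 h), 41.2 and 0.0262 (CTCF 45 min and 3 h), 2.34 and 3.94 (FOXA1), and 2.37 and 8.03 (Lamin B). With 50% overlap it was 24.7 (ER 45 min), 29.4 (CTCF 45 min) and 4.43 (FOXA1 45 min). With equal numbers it was, at 45 min and 3 h, 22.1 and 3.28 (ER), 35.0 and 4.88 (CTCF), 7.41 and 18.5 (FOXA1), 4.17 and 24.2 (Lamin B), and 86.5 for siNT in siCTCF. Without unplaced and Y sequences it was 23.5 and 8.09 (ER), 29.9 (CTCF 45 min) and 3.69 (FOXA1 45 min). Without regions of all 4 factors it was 18.4 and 5.44 (ER), 29.9 and 5.32 (CTCF), 2.84 and 9.82 (FOXA1), and 1.01 and 14.9 (Lamin B).

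CTCF at lost ER peaks no longer passed with lists cut at their median value (ratio 0.608) or 50% overlap (0.528), but passed with width matching (0.293) and the union of 3 times (0.606). FOXA1 at gained siCTCF peaks turned to 1.18 with lists cut at their median and 1.19 with width matching. Lamin B at CTCF peaks with ER at 0 h went from 0.910 to 1.08 with lists cut at their median and 0.604 without regions of all 4 factors. FOXA1 with Lamin B at 0 h turned to 0.668 with lists cut at their median and 0.400 with equal numbers, and was 1.01, not passing, without regions of all 4 factors. That cut removes peaks for lying in regions of every factor, so it lowers the number of overlapping peaks by construction. Folds and ratios need not fall with it. ER with CTCF at 0 h went from 44.7 to 47.2 times and ER with Lamin B at 3 h from 19.3 to 25.8.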

Other observations

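Places rich in peaks differed between kinds of list. Of the 31 windows of 1 Mb richest in Lamin B 45 min peaks, 10 lay on chromosome 20, 6 on chromosome 17, 5 on chromosome 1 and 4 on chromosome 3. Chromosome 16 had 2, and chromosomes 8, 10, 21 and Y had 1 each. The first was chromosome 3, 64000001 to 65000000, with 109 Lamin B peaks, followed by chromosome 20, 46000001 to 47000000, with 83. Of the peaks on assembled chromosomes these windows held 26.7% (25.4 to 28.1) of FOXA1 45 min peaks, 9.95% (9.31 to 10.6) of ER 0 h peaks and 5.75% (5.46 to 6.07) of CTCF 0 h peaks. They held 1.65% (1.53 to 1.78) of siNT ER peaks and between 0.542% and 1.45% of the peaks in the 5 lists without unplaced sequences. Chromosome X had from 1.20 to 1.72 times the mean density in those 5 lists and from 0.486 to 0.834 times in the other 7. No explanation of the difference on chromosome X was tested.

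Of all peaks in a list, unplaced sequences held 13.4% of FOXA1 45 min peaks, 12.2% of Lamin B 45 min peaks and 6.67% of ER 0 h peaks, and 0.0273% of siNT peaks. Regions with a time-course peak of all 4 proteins, each at any of the 3 times, numbered 5234. They held from 5.44% (FOXA1 0 h) to 22.3% (FOXA1 3 h) of the peaks of the time-course lists. They also held 0.253% of siNT and 0.237% of siCTCF ER peaks. The regions were chosen for their time-course peaks, so a higher share of those lists is partly built in.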
